A study of Marchantia polymorpha with 6 samples.

How the data were processed

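Messenger RNA was sequenced from thalli of Marchantia polymorpha, a liverwort whose main plant body, the thallus, is haploid. There were 6 libraries, 3 from the male wild-type accession Tak-1 and 3 from Mpbes1, a mutant made with CRISPR/Cas9 in the gene for the transcription factor BES1. BES1 belongs to the BES1/BZR1 family, best known from brassinosteroid signalling in flowering plants. Per the labels' protocols, plants of 30 days grew on solidified medium under 50 µmol/m2/s of white light for 16 h at 22 °C and 8 h of darkness at 20 °C. About 100 mg of thallus with apical notches was taken per sample, RNA integrity numbers were above 7, and libraries were made with a strand-specific poly(A) kit. The series' design text states that the 3 samples of a genotype were different plants and independent biological replicates.

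The authors deposited 1 table of raw read counts per gene, whole numbers with no normalization, for 19287 gene models in 6 columns of samples. The column layout is that of featureCounts, per the file headers. The submitters' processing notes name STAR 2.5.2b, featureCounts 1.5.1 and edgeR. The strand setting, the treatment of reads with several alignments and the genome build are not given in the sources used here. Gene identifiers end in v3.1, and the models lie on numbered scaffolds and on sequences named Chr_Y_A and Chr_Y_B, per the file headers. All coordinates are those of the deposited table, counted from 1. The exon length of each gene model is also the deposited value. Because the strand setting is unknown, reads of overlapping genes on opposite strands may not have been separated, and reads of near-identical copies may have been discarded or shared.

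The deposited identifiers could not be paired with gene names. The reference table used here lists genes of another assembly, MpTak2_v7.1, and 0 of the 19287 identifiers occur in it. Genes are therefore described by position, exon structure and expression, and at most 2 identifiers that rose and 2 that fell are printed. The targeted gene was not analysed here for the same reason, so its transcript level could not be used to check the labels. Of 27 gene lists fixed before the data were examined, those that need a gene name or a protein sequence could not be filled. The list of sex-chromosome genes was the only one that could. It was to hold sequences named V or U. It was applied to Chr_Y_A and Chr_Y_B, since Y is the older name of the male V chromosome. The planned promoter motif test and GC correction need a genome sequence and were not run.

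The test between genotypes was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, TMM normalization, filterByExpr) over all 6 libraries with genotype as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A change of at least 2-fold means such a call with an absolute log2 fold change of at least 1. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Expression is given as CPM, counts scaled by the TMM-adjusted library size, unless stated otherwise. The list of sex-chromosome genes was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2. The rule for named genes, fixed beforehand, takes the largest rise and fall by fitted log2 fold change among called genes whose 3 Mpbes1 values all lie to 1 side of the 3 Tak-1 values and whose mean is at least 5 CPM. It also takes the genes with the smallest p in each direction, and the limit on identifiers leaves 1 of each kind.

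Groups based on gene structure and position were chosen after the data were seen. Exon blocks are the exons of all isoforms of a model, merged where they overlap. Short scaffolds hold at most 5 gene models of the table. A run is a series of tested genes next to each other on a scaffold that all rose, or all fell, at least 2-fold. Runs of 4 or more were listed. The number of neighbouring pairs changed the same way was compared with 1000 random reorderings of the calls over the tested genes. Shares of genes have exact (Clopper-Pearson) 95% binomial intervals. For comparisons by expression, the tested genes were cut into 5 classes of equal size by mean expression over all libraries. Odds ratios come from the Mantel-Haenszel method within these classes or from Fisher's exact test, two-sided. These tests run across genes, which are not independent replicates. A gene counts as detected in only 1 genotype when the other genotype has at most 3 counts over its 3 libraries and each library of the first has at least 10. A fold against a group with 0 counts is a lower bound, the mean CPM of the other group over the CPM of 3 counts over the group at 0.

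Total counts ranged from 11597664 to 17741253 per library, and a count of 0 in a library allows a level of up to 0.166 to 0.266 CPM, depending on the library. Intervals and limits cover counting error only. No 2 libraries were duplicates: within a genotype, the chi-square per degree of freedom between libraries was between 2.98 and 10.5. The fit was tested on simulated data drawn from the real means and library sizes, with 200 of the genes changed. In that simulation of the Mpbes1 against Tak-1 comparison, 12272 genes were tested. It recovered 74.6% of 67 genes changed 1.5-fold, 91.0% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, and 10 of 184 calls were false. The changed genes were few and about evenly split between rises and falls, whereas 40.4% of the genes tested were called in the real comparison. The simulation therefore does not test the scaling or the share of false calls for changes that widespread. Alternatives were other scalings (RLE factors, library size only), other filters, DESeq2 1.42.0, limma-voom, a trend on gene length removed as an offset, a minimum effect in the test, the replicate number as a block, and leaving out each library in turn. Thinning of every library to the smallest total, other definitions of neighbours and other limits for genes detected in only 1 genotype were added after the data were seen. Figures were drawn with matplotlib 3.10.9.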

Results

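The data set held 6 poly(A) RNA libraries, 3 from thalli of the wild-type accession Tak-1 and 3 from thalli of the CRISPR mutant Mpbes1. Totals in Tak-1 were 13609401, 12857679 and 11650752 counts, and in Mpbes1 they were 11597664, 12653134 and 17741253. At least 1 read was seen for 14686 ± 94.0 gene models in Tak-1 and 14497 ± 186 in Mpbes1 (SD, n = 3), and 3025 of the 19287 models had no read in any library. The 10 most abundant genes took 5.69% ± 0.12 of the counts in Tak-1 and 5.36% ± 0.12 in Mpbes1 (SD, n = 3). The libraries separated by genotype. The first principal component held 90.6% of the variance of log2 CPM and the second 3.24%. Spearman correlations over tested genes were 0.991 to 0.997 within a genotype and 0.926 to 0.941 between genotypes.

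The comparison of Mpbes1 with Tak-1 asks which thallus transcripts differ in level between the mutant and the wild type. Of 12313 genes tested, 2380 rose and 2597 fell in Mpbes1, together 40.4% of those tested. Which direction had more calls depended on the scaling, with 2805 rises and 2294 falls by library size only and 2749 and 2395 with a trend on gene length removed. Most of these changes were small, with a median absolute log2 fold change of 0.56 among called genes. At least 2-fold changes were found for 1442 genes, of which 560 rose and 882 fell. The genes that rose at least 2-fold took 0.586% ± 0.015 of all counts in Tak-1 and 2.84% ± 0.25 in Mpbes1 (SD, n = 3). Those that fell took 4.11% ± 0.21 in Tak-1 and 1.35% ± 0.02 in Mpbes1. These sums describe genes chosen for their change, so no separate test was made. A test against a log2 fold change of 0.5 called 1654 genes, 663 that rose and 991 that fell, and with a filter of at least 5 CPM in 3 libraries 532 genes fell at least 2-fold. All calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the biological coefficient of variation between plants was 8.89%. Overlap with a gene model on the opposite strand affected 56 of the 1442 genes, for which reads of both genes may be mixed.

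**Figure D1:**
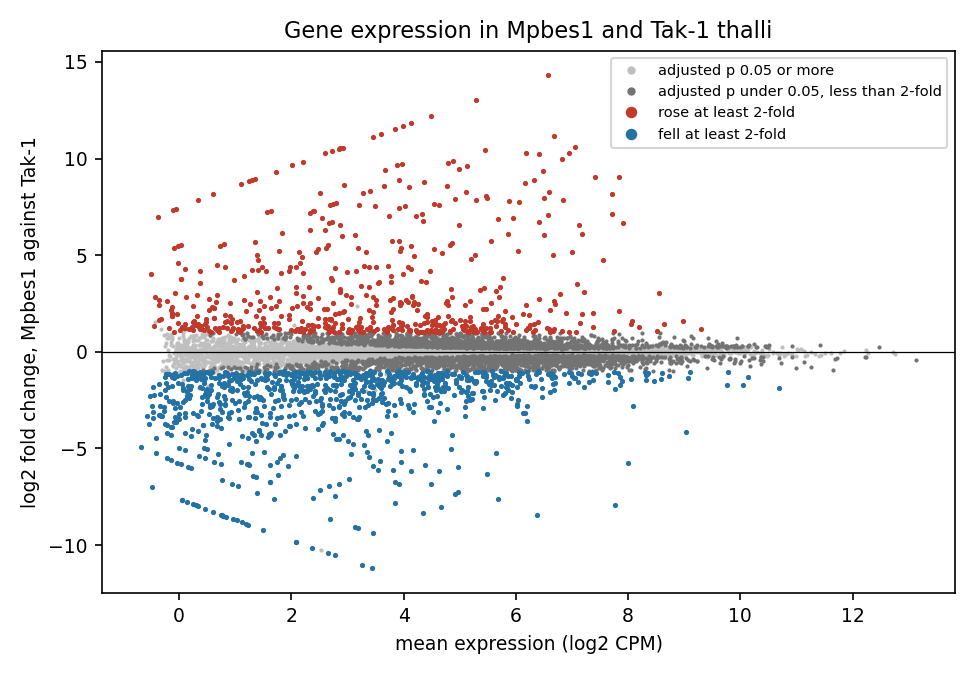
Each point is 1 of 12313 tested genes, with mean expression (log2 CPM) on the x axis and the log2 fold change of Mpbes1 against Tak-1 on the y axis. Red points are the 560 genes that rose at least 2-fold and blue points the 882 that fell. The straight rows of points at the upper and lower edges are genes without reads in 1 genotype, whose fitted fold change depends on the prior count.

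Large changes were more common among the genes that rose. With mean levels raised to that of 3 counts over a genotype where they lay lower, 122 of the 560 rising genes (21.8%) changed at least 32-fold, against 88 of the 882 falling genes (9.98%). The odds ratio was 2.51 (95% interval 1.85 to 3.43, Fisher's exact test across genes, two-sided, p = 1.0e-09). At a limit of 8-fold the numbers were 198 rising genes (35.4%) and 236 falling genes (26.8%), a smaller contrast in the same direction. Because weakly expressed genes cannot show a large fold, and more of the falling genes were weakly expressed, expression level and direction are not separated in this test.

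The rule for named genes gave 4 genes. Mapoly0016s0173.v3.1 rose with the smallest p. It lies on the plus strand of scaffold_16, from 1676201 to 1678341, with 2 exon blocks. Its level was 0.984 ± 0.052 CPM in Tak-1 and 228 ± 26.2 CPM in Mpbes1 (SD, n = 3), a log2 fold change of 7.84 ± 0.15 (SE; edgeR adjusted p = 3.3e-10). Mapoly0024s0073.v3.1 fell with the smallest p. It lies on the plus strand of scaffold_24, from 922131 to 924207, also with 2 exon blocks, and went from 434 ± 59.8 CPM in Tak-1 to 1.75 ± 0.24 CPM in Mpbes1 (SD, n = 3). Its log2 fold change was -7.92 ± 0.15 (SE; edgeR adjusted p = 3.5e-10).

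The rule ranks by the fitted fold change, which depends on the prior count for genes at 0 counts in 1 genotype, so the order among the strongest changes is not settled. The gene it took as the largest fitted rise was Mapoly0025s0043.v3.1, on the minus strand of scaffold_25 from 747522 to 748982. It had 0 counts in Tak-1 and 8362 counts in Mpbes1, 189 ± 51.7 CPM (SD, n = 3), and was at least 2368-fold higher in the mutant. The gene it took as the largest fitted fall was Mapoly0027s0190.v3.1, a gene with 1 exon block on the minus strand of scaffold_27 from 1820191 to 1821352. It had 831 counts in Tak-1, 22.0 ± 3.34 CPM (SD, n = 3), and 0 in Mpbes1, and was at least 312-fold lower in the mutant. Neither gene overlaps another model of the table.

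Some genes were detected in only 1 genotype. By limits chosen after the data were seen, there were 62 detected in Mpbes1 alone and 72 in Tak-1 alone, and in 25 and 29 of these the silent genotype had 0 counts over its 3 libraries, which allows up to 0.0799 CPM in Tak-1 and 0.0704 CPM in Mpbes1. Genes of the mutant-only group had the higher levels where they were expressed. Their median was 12.4 CPM and their maximum 204 CPM, against a median of 3.30 CPM and a maximum of 22.2 CPM in the group found in Tak-1 alone. The difference of the mean log2 levels was 1.57 (permutation test across genes, 100000 resamples, two-sided, p = 1.0e-05, the smallest it can give). The mutant-only genes lay on 41 scaffolds and the others on 54, and 31 and 40 of them had 1 or 2 exon blocks. With at least 30 counts in each expressing library, 86 genes were left over both groups.

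Genes that changed at least 2-fold lay next to each other on the scaffolds more often than by chance. Among 11848 pairs of neighbouring tested genes, both members changed in the same direction in 248 and in opposite directions in 75. Random reorderings of the calls gave a mean of 85.1 pairs changed the same way and at most 113 (permutation test, 1000 reorderings, p = 0.0010, the smallest it can give). With at least 5 CPM in 3 libraries the pairs changed the same way numbered 132, with the same p. There were 15 runs of 4 or more such neighbours, against at most 3 in 100 reorderings. With at least 5 CPM in 3 libraries, 6 of the 15 runs kept 4 or more called members, and with 1 library left out 11 to 15 did. They held 75 genes, 34 in 6 runs that rose and 41 in 9 runs that fell.

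The longest run lies on scaffold_35 from 841433 to 932785, over 91.4 kb. It holds 12 gene models, all on 1 strand, 10 of them with 2 exon blocks, and their exon lengths are between 572 and 887 bases. All 12 rose. Their summed level was 1.85 ± 0.25 CPM in Tak-1 and 499 ± 120 CPM in Mpbes1 (SD, n = 3). Of the 12, 4 had 0 counts in Tak-1, and with those at their lower bounds the log2 fold changes ran from 5.31 to 9.86 with a median of 8.11. No gene model without a call lies inside this run. A run of 6 rising genes on scaffold_25, from 675210 to 748982, went from 0.687 ± 0.112 to 931 ± 214 CPM in sum (SD, n = 3). It includes Mapoly0025s0043.v3.1, and 5 of its 6 members have 2 exon blocks and lie on the same strand. On scaffold_59, 4 genes with 2 exon blocks each, between 132987 and 145064, went from 0.179 ± 0.166 to 42.0 ± 8.80 CPM (SD, n = 3). On scaffold_53, 4 genes between 928826 and 940741 went from 49.4 ± 3.59 to 581 ± 98.3 CPM.

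**Figure D2:**
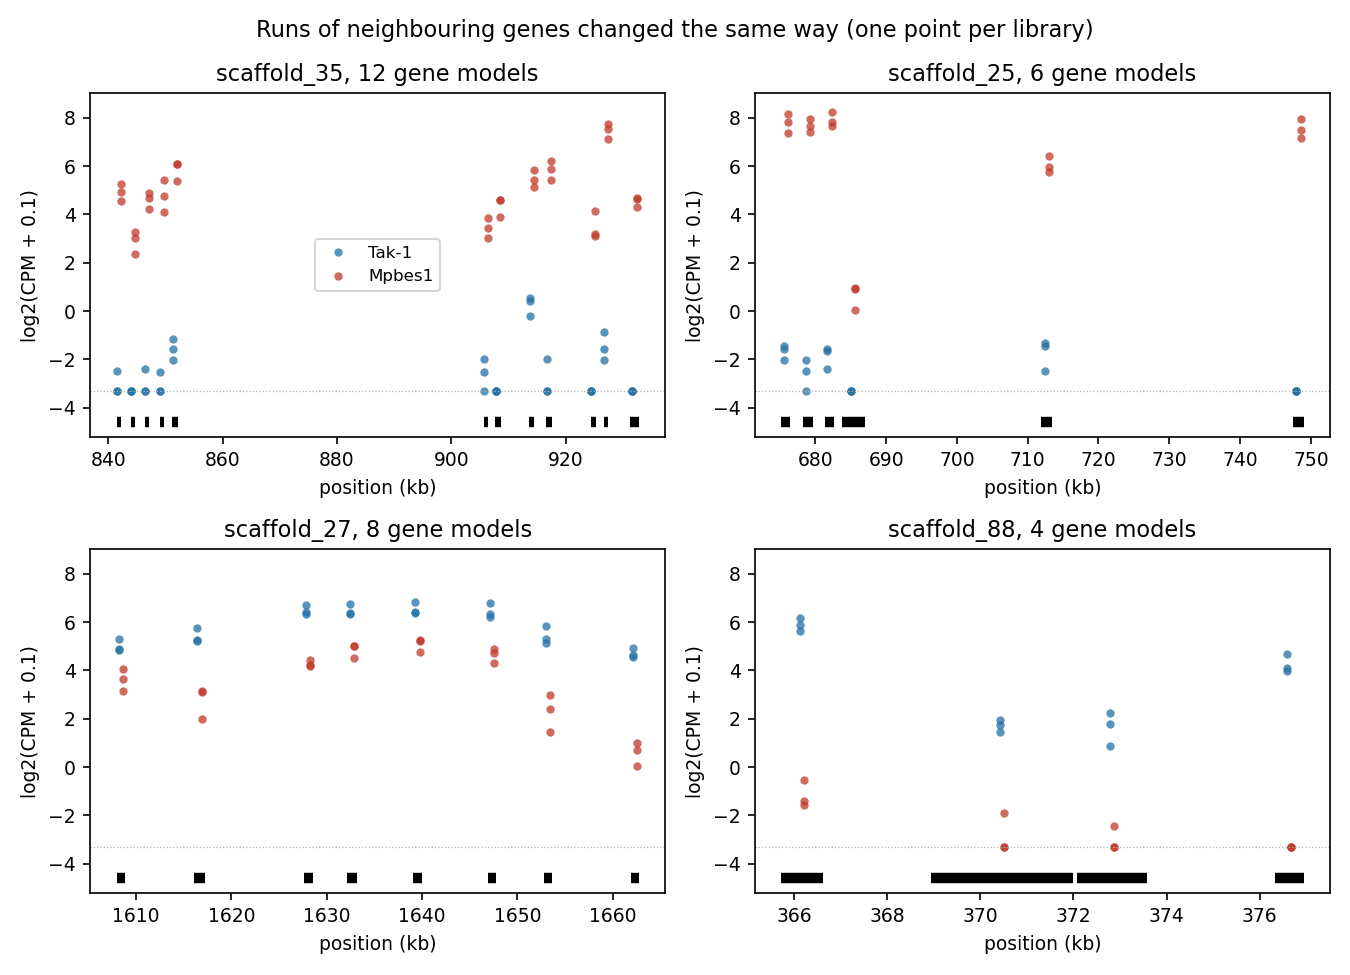
Levels of the genes in 4 runs, as log2(CPM + 0.1) on the y axis against position on the scaffold in kb on the x axis. Each point is 1 library, blue for Tak-1 and red for Mpbes1 (3 each), black bars mark the gene models and the dotted line marks 0 CPM. The 12 genes of scaffold_35 and the 6 of scaffold_25 are higher in every Mpbes1 library, and the 8 of scaffold_27 and 4 of scaffold_88 are lower.

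The longest run of falling genes lies on scaffold_27 from 1607951 to 1662748. Its 8 members all have 2 exon blocks and exon lengths of 573 to 940 bases. In sum they fell from 507 ± 93.4 CPM in Tak-1 to 133 ± 26.1 CPM in Mpbes1 (SD, n = 3). Their log2 fold changes ran from -4.23 to -1.39 with a median of -2.03, so the members of this run kept reads in the mutant. A run on scaffold_88 from 365722 to 376947 fell almost to the limit of detection, from 86.1 ± 16.8 to 0.453 ± 0.341 CPM over 4 genes (SD, n = 3), of which 2 were tested and called with at least 5 CPM in 3 libraries. On scaffold_193, 4 genes between 148829 and 166754 fell from 114 ± 19.4 to 5.16 ± 1.80 CPM. On scaffold_54, 5 genes of 6 or 7 exon blocks between 1169624 and 1219880 fell from 74.5 ± 21.1 to 18.8 ± 7.87 CPM. Only 3 of those 5 kept a 2-fold call without the second Mpbes1 library. A run of 4 on scaffold_121 was carried by a large spread, 50.4 ± 39.2 CPM in Tak-1 against 1.87 ± 1.10 CPM in Mpbes1, and kept 1 or 2 calls when any Mpbes1 library was left out.

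The share of genes that changed depended on expression level and exon number. In the lowest of 5 equal classes of mean expression, up to 8.87 CPM, 10.4% of 2463 genes rose at least 2-fold (95% interval 9.25 to 11.7) and 20.7% fell (19.1 to 22.3). In the highest class, above 92.0 CPM, 1.91% rose (1.41 to 2.53) and 2.31% fell (1.76 to 2.99). Falls per rise were 1.98 in the lowest class and between 1.13 and 1.28 in the others. Among changed genes, the odds of a fall were higher in the lowest class by a ratio of 1.61 (95% interval 1.29 to 2.003, Fisher's exact test across genes, two-sided, p = 1.4e-05). With at least 5 CPM in 3 libraries, falls per rise in the lowest class of the genes then tested were 1.503, and the odds of a fall no longer passed the test (Fisher's exact test, two-sided, p = 0.085). Genes with few exon blocks changed more often. With 1 exon block, 6.09% rose and 11.8% fell, and with over 10 exon blocks 1.70% rose and 2.03% fell. Within classes of expression, genes with 1 or 2 exon blocks had 1.41 times the odds of a change of at least 2-fold (95% interval 1.25 to 1.59, Mantel-Haenszel).

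Genes on short scaffolds, those with at most 5 gene models, changed more often than genes elsewhere. Of 273 tested, 30 rose (10.99%) and 58 fell (21.2%) at least 2-fold, against 4.40% and 6.84% of the 12040 genes on larger sequences. Within classes of expression and exon number the odds ratio for a fall was 2.06 (95% interval 1.51 to 2.82, Mantel-Haenszel, across genes) and for a rise 1.66 (1.12 to 2.46).

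**Figure D3:**
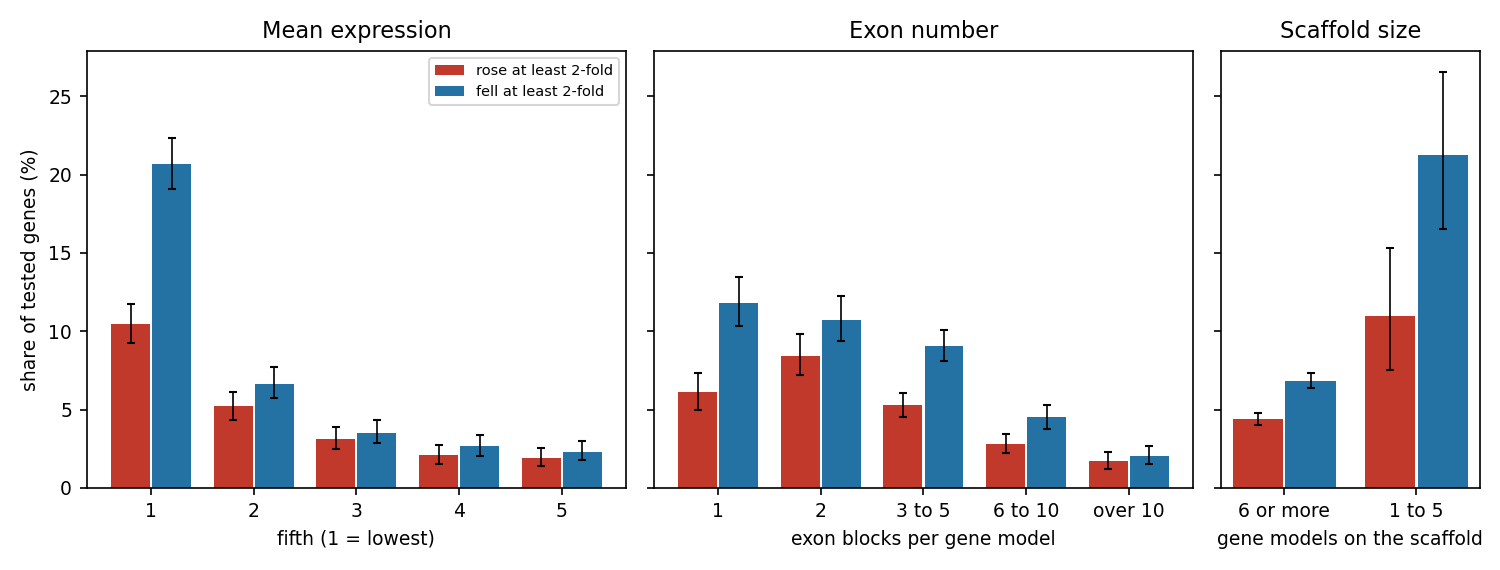
Share of tested genes (%, y axis) that rose (red) or fell (blue) at least 2-fold in Mpbes1, by class of mean expression, by number of exon blocks and by number of gene models on the scaffold. Error bars are exact 95% binomial intervals. Falls reach 20.7% in the lowest class of expression and 21.2% on scaffolds with 1 to 5 gene models.

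Reads of gene models on the male sex chromosome were present in both genotypes at shares that differed by little. The table holds 113 models on Chr_Y_A and Chr_Y_B, and their reads made up 0.196% ± 0.004 of the counts in Tak-1 and 0.201% ± 0.002 in Mpbes1 (SD, n = 3; exact permutation test, two-sided, p = 0.20, with 0.10 the smallest p possible for 3 against 3). Of 31 that could be tested with edgeR, 0 rose and 5 fell with adjustment over all genes. Of all 12313 genes tested 2380 rose and 2597 fell. Among calls of any size, falls were thus not more common on the list than over all genes, and rises were less common. Of the 5 that fell, all but the gene with a log2 fold change of -0.92 fell at least 2-fold, against 882 of the 12313. At that limit the share of falls was higher on the list, a difference that was not tested. The counts of 0 rises and 5 falls of any size were the same adjusted over the list alone and with DESeq2 and limma-voom. At an unadjusted p under 0.05, 3 rose and 5 fell. In 22 of the 31 the log2 fold change was within 0.25 of 0, and the median was -0.01. The 5 that fell are described here after their values were seen, and none had a mean above 10.1 CPM in Tak-1. The gene at Chr_Y_A 3256741 to 3276682 fell from 1.12 ± 0.14 to 0.099 ± 0.052 CPM and the gene at Chr_Y_B 1903668 to 1908221 from 2.56 ± 0.13 to 0.702 ± 0.160 CPM (SD, n = 3). The genes at Chr_Y_A 2268250 to 2269704 and 2272264 to 2273529 had log2 fold changes of -0.92 and -1.06, and the gene at Chr_Y_B 2453675 to 2458281 one of -1.05. The list as a whole did not pass the test against other genes (camera, p = 0.46; p = 0.51 with an estimated correlation), and with at least 5 CPM in 3 libraries its direction turned. The mean log2 fold change over the list was -0.26. By fry, which asks only whether the genes of the list move on balance in 1 direction, the p for a fall was 0.0055.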

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

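Thinning, the other definitions of neighbours and the other limits for genes detected in only 1 genotype were tests chosen after the results were seen. Between the 30 results recomputed and their settings there were 478 alternative values, of which 451 kept their direction and their side of the threshold or stayed within 1.5 times of the reported count. The number of called genes was 3974 to 4808 with 1 library left out (1795 to 2260 rose, 2087 to 2548 fell), with 547 to 582 that rose and 828 to 972 that fell at least 2-fold. It was 4977 with RLE factors, 5099 with library sizes only, 4481 with DESeq2, 4971 with limma-voom, 5144 with the length offset and 4851 after thinning, and 4963, 4674, 4368, 4898, 4577 and 4730 of these were among the 4977. The share of calls that rose, 47.8%, was 55.0% with library sizes only, 53.4% with the length offset, 53.3% with the length offset and the replicate block, and 40.1% when tested against a log2 fold change of 0.5, so that which direction had more calls depended on the setting. A test against a log2 fold change of 0.5 called 1654 genes, 663 that rose and 991 that fell, because it asks for a larger effect. With at least 5 CPM in 3 libraries, 10717 genes were tested instead of 12313. Of these 532 fell at least 2-fold, against 882, and 132 neighbouring pairs changed the same way, against 248. The filter leaves out weakly expressed genes, among which changes of at least 2-fold were most common. Neighbouring pairs numbered 1255 when calls of any size were counted (970.0 by chance) and 188 without the runs of 4 or more (77.5 by chance), and 242 to 274 with 1 library left out. Whether the replicate numbers pair the samples was not settled. Same-numbered deviations correlated weakly, at 0.17, -0.03 and 0.14, but 4 of the 6 libraries correlated best with their own number. The replicate block gave 5246 calls, 4884 of them among the 4977, and 5515 together with the length offset. For the sex-chromosome list the direction turned with at least 5 CPM in 3 libraries, where the p of camera in limma was 0.61 and the cause was not tested. It was 0.294 to 0.569 with 1 library left out, and the p of fry, which does not compare the list with other genes, was 0.0055. The count of genes detected in only 1 genotype was 134, 54 when the silent genotype had to have 0 counts and 86 with at least 30 counts in the other. The ratio of falls to rises in the lowest class of expression was 4.26 with no filter and 1.503 with the stricter filter. Of the 15 runs, 6 kept 4 or more called members with at least 5 CPM in 3 libraries, 12 with no filter, 13 with DESeq2 and 11 to 15 with 1 library left out, while the runs on scaffold_35 and scaffold_27 kept all 12 and 8 members in every fit in which they were counted. The planned results for the targeted gene, promoter motifs and GC content were not run, and depth limits statements on genes up to 0.266 CPM.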

Other observations

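The tests of equal fold changes within runs, of reads in the lower genotype and of 1 ratio over the Tak-1 libraries were chosen only after the result was seen.

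Neighbours of like structure, on the same strand with the same number of exon blocks and exon lengths within 1.5 times, shared a change far more often than unlike neighbours. When at least 1 gene of a pair changed at least 2-fold, both changed the same way in 53 of 124 like pairs (42.7%) and in 195 of 2175 unlike pairs (8.97%). The unlike pairs still exceeded the 3.26% that random reorderings gave (permutation test, 1000 reorderings, p = 0.0010, the smallest it can give).

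For the runs of neighbouring genes 3 explanations were set against each other. Counting of the same reads for every copy would give members of a run equal fold changes. In 86.7% of the 15 runs the members differed beyond their standard errors, with members at 0 counts in 1 genotype left out. These errors, derived from the F statistic, can be too small for members with few reads, so this share may be too high. A member on scaffold_35 at 0, 0.078 and 0 CPM in Tak-1 had a standard error of only 0.44. Some runs mix unlike gene models, such as scaffold_49 with 1 to 16 exon blocks, so a difference there decides nothing. Members did differ in the runs of similar models on scaffold_35 and scaffold_27. On scaffold_35 the members with the most Tak-1 reads had log2 fold changes of 5.31 ± 0.26 and 9.33 ± 0.32 (SE). They did not on scaffold_54 and scaffold_121 (chi-square test of heterogeneity, p = 0.26 and 0.91), where such counting stays open. Absence of a whole run from the genome of 1 genotype would leave no reads. A member counted as detected with a read in each library of the lower genotype and 10 counts or more over them. At least 1 member was detected in 13 of the 15 runs. This argues against absence where every member was detected, as for all 8 on scaffold_27. It does not exclude absence where few were, such as 1 of 4 on scaffold_88, at 0.592, 0.236 and 0.277 CPM in Mpbes1. So few reads may be those of near-identical copies elsewhere. For the 31 of the 75 members not detected by this rule, low expression and absence of their part of the run cannot be told apart. Their counts are at or near 0 and no genome sequence of either genotype was used here. Like and unlike neighbours, in runs or not, differed by 33.8 percentage points (permutation test, 100000 resamples, p = 1.0e-05, the smallest it can give). For like neighbours this is what would be seen if tandem copies responded together to the genotype. Part of the reads of near-identical copies may still be shared. Most of the excess over chance lay outside like pairs, with 195 unlike pairs against 82.5 by chance and 53 like pairs against 2.55. The test of like structure does not cover that part. Copies on opposite strands or with another exon number count as unlike, and no sequences were compared. On scaffold_59, for example, 4 genes of 2 exon blocks lie on both strands. Whether tandem copies account for the unlike pairs was therefore not settled.

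The more frequent falls on short scaffolds have the following limits. The chi-square per degree of freedom of the counts of the 58 fallen genes over the 3 Tak-1 libraries was 11.6, but pairs of Tak-1 libraries gave 9.23 to 10.5 over all genes, so this value decides nothing on a foreign source of RNA in the Tak-1 plants. The odds ratio for a fall was 3.67 without classes (Fisher's exact test) and 2.06 within classes of expression and exon number, with a lower 95% bound of 1.51. The excess thus remained within these classes, which are wide. The lowest class of expression runs from 0.626 to 8.87 CPM, and exon number was split only at 1 or 2 blocks against 3 or more. Low expression and few exons may therefore still account for more of the excess. A foreign source, reads shared between repeated sequences and a biological difference between the genotypes stay open, and the latter 2 were not tested.

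The excess of falls over rises among weakly expressed genes was not explained by depth or by scaling. With every library thinned to the smallest total, falls per rise in the lowest class of expression were 1.96, and the lowest value under the other scalings was 1.86. A biological difference between the genotypes stays open and was not tested.

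The 6 libraries can be split into 3 against 3 in 10 ways. The genotype split called 4977 genes with edgeR and the highest of the other splits called 0, with 65 to 419 genes at an unadjusted p under 0.05 in those and 5976 in the genotype split. Each of the other splits put libraries of both genotypes in each group, so the genotype difference widened the spread within groups. Few calls would follow there in any case, so these splits do not measure how many calls chance gives. Only 1 of the 10 splits reached the count of the genotype split, and 10 splits are too few for a share under 0.05.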
